A study of Arabidopsis thaliana with 54 samples.

How the data were processed

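The deposited unit was the unnormalised read count per gene and library, and per the labels each count file held 1 library of roots or rosettes. Per the submitters' processing notes, reads were aligned with Bowtie to TAIR10 and counted with HTSeq, with no versions given for these tools. The deposited counts covered 33610 gene identifiers in each of 54 libraries, and whole numbers without scaling were checked before use. The strand setting of the counting was not given, and genes with near-identical copies (LHCB, RBCS and ferritin genes) share reads. Of the identifiers, 28932 matched a locus tag of the TAIR10.1 reference, which was used for names alone, 4678 had no tag there and 10626 carried a gene symbol.

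The labels call the 3 libraries of a group biological replicates, and nothing in them says that replicates came from separate containers or separate harvests. Replicates are therefore only what the labels call separate samples, and every p value measures the spread between these samples, which may be partly technical. The 18 groups combined 2 tissues, 2 genotypes and 4 treatments of 3 days, plus a second spl7 control. Per the labels, Col-0 was pretreated with 0.1 µM copper and spl7 with 2.5 µM, except the second spl7 control (0.1 µM, alone titled Ex). A comparison of the response of spl7 with that of Col-0 therefore also compares pretreatments. Any comparison with the second spl7 control also compares the Ex libraries with the others.

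Each tissue was fitted separately with all 27 libraries (R 4.3.3, edgeR 4.0.16 quasi-likelihood test, limma 3.58.1, DESeq2 1.42.0). Genes with low counts were removed with filterByExpr (minimum count 10, minimum total count 15), which kept 20462 genes in roots and 20015 in rosettes, and libraries were scaled with TMM factors (0.969 to 1.035 in roots, 0.865 to 1.16 in rosettes). Residual degrees of freedom were 18 per tissue. The 24 comparisons, 12 per tissue, were chosen before the data were examined: 6 treatments against the control of the same genotype, spl7 against Col-0 after the same pretreatment, spl7 after low-copper against high-copper pretreatment, 3 differences between the responses of the genotypes, and the departure of the doubly deficient Col-0 group from the sum of the single deficiencies. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within its comparison. Changes are log2 changes ± standard error, the latter being the absolute log2 change over the square root of the F statistic of the edgeR test. Levels are CPM (the count scaled by the effective library total), mean ± SD.

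A list of genes was tested with camera at its preset correlation of 0.01, with camera at the correlation estimated from the data, and with fry, if at least 5 members were measured. The 24 lists, with 322 members, were written from general knowledge: copper deficiency genes under SPL7, copper proteins targeted by copper microRNAs, copper chaperones and ATPases with plastocyanin, iron uptake, iron regulators, iron storage, zinc deficiency, photosynthesis, chlorophyll and heme synthesis, jasmonate, salicylate, ethylene, oxidative stress, circadian clock, phosphate starvation, sulfate assimilation, aliphatic glucosinolate synthesis, anthocyanin synthesis, senescence, root hair, endodermis, xylem, leaf markers and root markers. Some lists share members: photosynthesis and leaf markers share LHCB2.1, LHCB1.1 and PETC, root markers and root hair share COBL9 and EXPA7, and root markers and endodermis share CASP1. Root markers had too few measured members in rosettes for a list test. List members were also adjusted over the list alone. A further 3 lists (low oxygen, abscisic acid and desiccation, touch and wounding) were chosen after values of their members were seen.

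Named genes followed a fixed rule. SPL7 was given in every group. For each list and comparison up to 4 called members with the largest changes were eligible, and for the copper and iron lists any detected member. The 5 largest rises and 5 largest falls of a comparison were also eligible if the mean reached 1 CPM in a group and the replicates of the compared groups did not overlap. Where every library of a group had a count of 0, the fold is given as a lower bound against a floor of 3 counts per library. Where a group had only 1 to 3 counts in sum, the ratio of summed counts is given with its counting interval. These intervals and floors cover counting error alone.

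The choices to be varied were set in advance: DESeq2 size factors in the edgeR fit, the DESeq2 Wald test, no filter on low counts, the replicate number as a block, and leaving out each replicate in turn. Fits of only the compared groups, and of 26 root libraries without replicate 3 of iron-free spl7, were added after the results were seen. Regroupings of the libraries (splits) were set in advance.

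Simulated data with 100 planted genes per fold tested each comparison. In roots 63 to 94 of the genes planted at 2-fold were found (median 86) and 92 to 100 of those at 4-fold, with a median of 6 and at most 50 false calls. In rosettes 69 to 92 (median 85) and 92 to 99 were found, with at most 13 false calls. No sign was wrong. Planted lists were called in 12 of 12 comparisons per tissue, unplanted in 0. Rates cover planted genes only, not camera's preset if real genes correlate more than simulated ones.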

Results

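RNA was sequenced from roots and rosettes of Arabidopsis Col-0 and of the insertion line spl7, in 54 libraries of 18 groups (n = 3 libraries per group). Hydroponic plants were moved for 3 days to a control solution (25 µM iron, 0.5 µM copper), a copper-free solution, an iron-free solution or a doubly deficient solution without either metal. Each tissue held 9 groups, because spl7 had a control after each of its pretreatments. Library totals were 9.25 to 17.28 M counts in roots (median 13.56) and 11.69 to 20.06 M in rosettes (median 15.01). The biological coefficient of variation was 0.129 in roots and 0.104 in rosettes. Every gene described as having risen, fallen or changed, or as higher or lower in a group, had an adjusted p below 0.05 in the edgeR test, and plain values after a gene are log2 changes ± standard error. Lists are given as members called over all genes, then with adjustment over the list alone, with the camera adjusted p and that with an estimated correlation (p_est), and ratios are of summed counts with counting intervals. LOO is the range of calls with 1 library left out, W and C are the calls by the DESeq2 Wald test and by an edgeR fit of only the compared groups, and R those from 26 root libraries, without replicate 3 of iron-free spl7.

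SPL7, the transcription factor gene that directs the copper deficiency response, was measured in every group to describe the insertion line. In roots its level was 71.9 ± 5.42 CPM in the Col-0 control, 61.8 ± 5.54 without copper, 72.5 ± 1.99 without iron and 66.7 ± 1.06 without both (SD, n = 3). In roots of spl7 it was 25.6 ± 3.03 in the control, 26.3 ± 1.44 in the control pretreated with low copper, 24.2 ± 0.84 without copper, 26.1 ± 0.946 without iron and 25.3 ± 1.21 without both (SD, n = 3). In rosettes of Col-0 it was 26.2 ± 3.3, 25.7 ± 0.928, 30 ± 1.06 and 24.4 ± 0.708 CPM in the same order, and in rosettes of spl7 11.6 ± 3.12, 16.3 ± 2.03, 10.7 ± 0.716, 12.7 ± 0.602 and 10.5 ± 0.702 (SD, n = 3). The SPL7 transcript was thus lowered and not absent: between controls with the same pretreatment it was 2.74-fold lower in roots (log2 change -1.45 ± 0.08, adjusted p = 6.19e-11) and 1.61-fold lower in rosettes (log2 change -0.69 ± 0.12, adjusted p = 7.18e-05). Within spl7 rosettes SPL7 rose with low-copper against high-copper pretreatment (log2 change 0.49 ± 0.13, adjusted p = 0.00748).

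The response of Col-0 roots to copper deficiency was asked first. FSD1, the iron superoxide dismutase that replaces the copper enzymes, rose from 70.8 ± 2 to 304 ± 9.67 CPM (log2 change 2.1 ± 0.19, adjusted p = 2.35e-06). The cupric reductase gene FRO4 rose from 9.12 ± 2.36 to 118 ± 36.8 CPM (log2 change 3.69 ± 0.30, adjusted p = 2.49e-07), and FRO5, a reductase of the same family, had a ratio of 185 (interval 62.7 to 898). AT1G71200 (CITF1), a transcription factor gene of copper uptake, rose by a log2 change of 3.77 ± 0.47, the metal transporter gene ZIP2 by 1.62 ± 0.21, and the copper chaperone gene CCH from 182 ± 6.41 to 482 ± 77.8 CPM. The copper transporter gene COPT2 stood at 15.2 ± 4.59 CPM with copper and 62.5 ± 7.62 without (log2 change 2.04 ± 0.52, adjusted p = 0.126). CSD1, a copper/zinc superoxide dismutase whose message is a microRNA target, fell (log2 change -0.80 ± 0.12), as did CCS, the copper chaperone of that enzyme (log2 change -0.52 ± 0.09). The clock genes LHY and PRR9, both expressed in the morning, fell by log2 changes of -1.63 ± 0.23 and -1.17 ± 0.23.

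Of 9 measured copper deficiency genes, 7 rose and none fell (9 and 0 over the list alone, camera adjusted p = 3.8e-66, p_est = 2.48e-10). Of 13 copper proteins targeted by microRNAs, 2 fell and none rose (6 and 0 over the list alone, camera adjusted p = 3.03e-05, p_est = 0.0153). Of 16 clock genes, 2 fell (5 over the list alone, camera adjusted p = 5.32e-06, p_est = 0.173). None of the 20 iron uptake genes passed (camera adjusted p = 0.00015, p_est = 0.379). No iron storage gene passed over all genes, and over the list alone 5 of 16 rose and 1 fell (p_est = 0.384). In all 15 genes were called, 10 higher and 5 lower, and 3262 genes had an unadjusted p below 0.05 (W 190, 91 higher and 99 lower; R 271, 136 and 135). W held 3 of the 9 copper deficiency genes. Without replicate 1 of the copper-free group 1518 genes were called.

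Iron deficiency in Col-0 roots was asked next. IRT2, an iron transporter gene of the root epidermis, rose by a log2 change of 4.14 ± 0.84 (adjusted p = 0.00241), and AT2G30766 (IMA3), which encodes an iron signalling peptide, by 4.52 ± 0.90 (adjusted p = 0.0019). Genes of iron mobilisation rose with them: the transcription factor genes MYB72 (3.06 ± 1.08) and MYB10 (2.06 ± 0.54), the coumarin glucosidase gene BGLU42 (1.40 ± 0.45), and the vacuolar zinc transporter gene MTPA2 (MTP3) (1.72 ± 0.60). The main uptake genes were scattered in the control, IRT1 at 309 ± 255 CPM against 1220 ± 127 without iron and the ferric reductase gene FRO2 at 231 ± 194 against 955 ± 109. The nicotianamine synthase gene NAS4 rose by 2.25 ± 0.70, the iron-responsive plastid gene CGLD27 by 2.08 ± 0.68 and AT1G74770 (BTSL1), which encodes a ubiquitin ligase that restrains the response, by 1.50 ± 0.34. Copper deficiency genes fell. FSD1 decreased to 1.01 ± 0.838 CPM (log2 change -6.08 ± 0.28, adjusted p = 2.41e-11), ZIP2 from 53.8 ± 11.2 to 5 ± 0.833 CPM (log2 change -3.42 ± 0.25), FRO4 by -1.24 ± 0.34, CCH by -0.79 ± 0.12 and the metal-nicotianamine transporter gene YSL2 by -0.78 ± 0.18. WRKY70, a regulator of salicylate defence, fell from 52.3 ± 19.1 to 10.4 ± 1.24 CPM (log2 change -2.33 ± 0.25). Also risen were AT1G52120, a lectin gene (4.76), and SQE6, a squalene monooxygenase gene (ratio 24.3, interval 8.02 to 121).

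Of 9 copper deficiency genes in iron-free Col-0 roots, 5 fell and none rose (6 over the list alone, camera adjusted p = 3.78e-14, p_est = 8.88e-05). Of 13 microRNA-targeted copper proteins, CSD2 (0.30 ± 0.09) and AT3G15640 (COX5B-1), a subunit of cytochrome oxidase (0.45 ± 0.12), rose and the laccase gene LAC13 fell (-0.87 ± 0.13; LOO 0 to 2 up, C 4), and among 8 chaperone and ATPase genes only the copper pump gene RAN1 changed (-0.38 ± 0.13). Of 20 iron uptake genes, 7 rose (LOO 2 to 7, C 15) and 1 fell (10 and 1 over the list alone, camera adjusted p = 0.000111, p_est = 0.486), and of 23 iron regulators 7 rose (LOO 2 to 10, C 12) and 2 fell (11 and 2 over the list alone, p_est = 0.486). Of 16 iron storage genes 2 fell, the metal-nicotianamine transporter genes YSL1 (-1.81 ± 0.41) and YSL3 (-0.74 ± 0.16). Zinc genes moved both ways, 3 up (LOO 1 to 2; ZIP9 by 1.32 ± 0.27, ZIP1 by 0.98 ± 0.25) and 3 down (ZIP3 by -1.2 ± 0.25, the zinc pump gene HMA2 by -1.05 ± 0.14) of 10. Root hair genes rose in 6 of 7 cases (LOO 3 to 6; 7 over the list alone, p_est = 0.207), among them the root hair regulator RSL4 (1.08 ± 0.33) and the wall protein gene PRP3 (1.08 ± 0.24).

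Sulfur-linked and defence genes were also called in these roots. Of 8 sulfate genes 4 fell (p_est = 0.207), including ATSDI1 (SDI1), which restrains glucosinolate synthesis under sulfur shortage (-1.61 ± 0.32), and the transporter gene SULTR1;2 (-0.89 ± 0.17). Of 14 aliphatic glucosinolate genes 6 fell and 1 rose (p_est = 0.391), with the chain elongation genes MAM1 (-1.34 ± 0.21) and IMS2 (MAM3) (-1.16 ± 0.15) among the falls. Of 14 salicylate genes 5 fell and 1 rose (6 and 2 over the list alone, p_est = 0.486), among the former SARD1 (-1.22 ± 0.17) and CBP60G (-1 ± 0.18), regulators of salicylate synthesis. Of 10 ethylene genes 1 rose (ACS2 1.38 ± 0.29) and 2 fell (LOO 0 to 3; ACS6 -1.14 ± 0.34), of 12 oxidative stress genes 1 rose and 2 fell (LOO 1 to 2; STZ (ZAT10) -1.93 ± 0.33), and of 16 clock genes 1 rose (ELF4 0.71 ± 0.22) and 5 fell (LOO 1 to 4; PRR9 -1.12 ± 0.22). Of 33 photosynthesis genes 2 fell (PSAN -0.92 ± 0.29, LHCA4 -0.67 ± 0.22, p_est = 0.568), and no leaf marker passed. In all 2034 genes rose and 2131 fell, 383 and 358 of them at least 2-fold. Against these 4165 calls (R 6482), 1456 were made without replicate 2 of the control, 1930 without replicate 2 and 1955 without replicate 3 of the iron-free group.

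Doubly deficient Col-0 roots were compared with the control to ask whether both responses add. FSD1 stood at 40 ± 8.03 CPM, between the single deficiencies, and fell by a log2 change of -0.82 ± 0.19 (adjusted p = 0.0158). The copper transporter gene COPT1 rose by 0.77 ± 0.18 and LAC13 fell by 0.80 ± 0.13. IRT1 was at 44.3 ± 72 CPM and FRO2 at 56.6 ± 84 CPM, and no iron uptake gene passed in edgeR (0 of 20, 0 over the list alone, median log2 change -0.87, camera adjusted p = 0.000652, p_est = 0.656). Among 23 iron regulators only bHLH115 changed (-0.31 ± 0.08). Among 9 copper deficiency genes COPT1 rose and FSD1 fell (p_est = 0.942). Salicylate genes fell in 5 of 14 cases (LOO 3 to 5; 6 over the list alone, p_est = 0.2): WRKY70 (-1.95 ± 0.25), ALD1, which makes the defence signal pipecolate (-1.82 ± 0.49), CBP60G (-1.37 ± 0.18) and SARD1 (-1.11 ± 0.17). Of 12 oxidative stress genes 3 fell (LOO 0 to 3, C 5; 5 over the list alone, p_est = 0.556), including the alternative oxidase gene AOX1A (-0.98 ± 0.19). Of 16 clock genes 3 rose (CCA1 by 1.08 ± 0.28, PRR9 by 0.70 ± 0.20) and 2 fell (LOO 0 to 1 up, 0 down; C 1 down). The sulfate reductase gene APR3 fell by 0.92 ± 0.16, the only call among 8 sulfate genes (5 over the list alone, p_est = 0.2). Also risen were genes known from low oxygen, AT4G33560 (4.66), the pyruvate decarboxylase gene AT4G33070 (3.21, adjusted p = 0.0364) and AT5G39890 (2.63), with the ethylene synthesis gene ACO1 (1.73 ± 0.49). In all 329 genes rose and 631 fell (50 and 143 at least 2-fold). Against these 960 calls (W 1473, C 2322, R 2667), 174 were made without replicate 2 of the control and 257, 424 and 309 without replicates 1, 2 and 3 of the doubly deficient group.

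**Figure D1:**
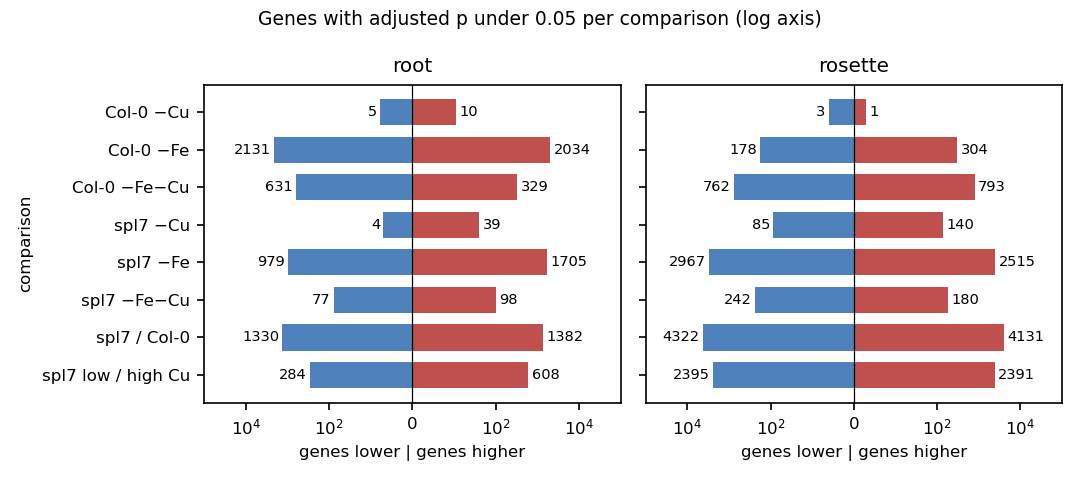
Numbers of genes called lower (blue) and higher (red) in each comparison of groups, on a logarithmic scale with the counts printed.

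Whether spl7 roots still answered a lack of copper was tested against the spl7 control. No copper deficiency gene and no member of any other list passed over all genes. FRO4 stood at 0.175 ± 0.159 CPM with copper and 0.387 ± 0.144 without. PRP1, a proline-rich wall protein gene, rose (3.22, adjusted p = 0.0391), as did AT1G13490 (1.84). OFP1 (-0.85), AT1G14630 (-0.84) and BAT1 (-0.49) fell. Over the list alone 4 of 14 salicylate genes rose (camera adjusted p = 6.37e-08, p_est = 0.139), as did 3 of 10 ethylene genes (p_est = 0.139) and 3 of 12 oxidative stress genes (p_est = 0.523). In all 39 genes rose and 4 fell, and 1740 had an unadjusted p below 0.05. Against the 43 calls, edgeR made 0 without replicate 1 of the control (1260 genes at an unadjusted p below 0.05), 0 without replicate 2 of the control (1270 genes), and 23 without replicate 2 of the copper-free group (W 169, R 355).

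In iron-free spl7 roots 16 of 23 iron regulators rose and 10 of 16 storage genes fell (LOO 14 to 16 and 3 to 12, p_est = 0.0847 for each), whereas a fit of only the compared groups called 0 genes with edgeR (2621 at an unadjusted p below 0.05). The phloem iron transporter gene OPT3 went from 20.5 ± 12.4 to 364 ± 269 CPM, AT2G30766 (IMA3) rose by a log2 change of 5.42 ± 0.91, NAS4 by 5.14 ± 0.72, the regulator gene BHLH100 by 5.08 ± 1.1 and AT1G47395 (IMA2) by 4.72 ± 1.01. IRT2 rose by 3.25 ± 0.83, the proton pump genes HA7 (AHA7) and HA2 (AHA2) by 1.31 ± 0.26 and 0.42 ± 0.11, and AT3G13610 (F6H1), which makes coumarins, by 0.83 ± 0.24. The ferritin gene FER1 fell from 140 ± 69.5 to 25.7 ± 22.3 CPM (-2.47 ± 0.48), FER4 by -1.85 ± 0.43, the vacuolar iron transporter gene AT1G21140 (VTL1) by -2.27 ± 0.70 and YSL1 by -2 ± 0.53. Among copper deficiency genes FRO4 rose to 2.13 ± 1.22 CPM (3.56 ± 0.74) and COPT2 by 2.58 ± 0.72, the only calls of 9. Copper proteins moved both ways, ARPN, a plantacyanin (2.03 ± 0.38), and LAC13 (0.92 ± 0.14) up and the lignin laccase genes LAC17 (-1 ± 0.14), LAC2 (-1.23 ± 0.21) and IRX12 (LAC4) (-0.85 ± 0.17) down, 3 and 3 of 13 (LOO 3 to 7 and 3 to 5), and the copper pump gene HMA5 rose by 0.58 ± 0.15. The replicates were unequal: OPT3 read 581, 447 and 63.6 CPM and FER1 13, 12.7 and 51.5 CPM in replicates 1, 2 and 3.

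Of the iron regulators in iron-free spl7 roots 1 fell (16 rose and 3 fell over the list alone, camera adjusted p = 3.05e-10). No storage gene rose (13 fell and 1 rose over the list alone), and of 20 uptake genes 4 rose (LOO 1 to 5, p_est = 0.682). Of 14 salicylate genes 8 rose (LOO 5 to 8, p_est = 0.189), among them BGL2 (PR2), a glucanase gene (3.04 ± 0.86), FMO1, which makes the systemic defence signal (2.13 ± 0.25) and PR5 (ratio 43.8, interval 11.8 to 367). Jasmonate genes rose in 5 of 19 cases (LOO 1 to 12; 9 and 1 lower over the list alone, p_est = 0.52), with AOC2 (2.92 ± 0.63), and oxidative stress genes in 4 of 12 (LOO 1 to 9; 8 over the list alone, p_est = 0.353), with GSTU24 (2.05 ± 0.41). All 5 xylem genes fell (p_est = 0.0847), including the protease gene XCP1 (-0.92 ± 0.15) and the cellulose synthase gene IRX3 (-0.83 ± 0.14). Of 7 endodermis genes CASP1 fell (-0.58 ± 0.19), which is also a root marker (5 over the list alone, p_est = 0.353). Of 9 root markers 3 fell (LOO 0 to 4) and the nitrate transporter gene NRT2:1 rose (2.77 ± 0.53). ACO1 (2.90 ± 0.50) and ACS2 (1.43 ± 0.29), both for ethylene synthesis, rose, as did ZIP1 (1.58 ± 0.25). Also risen were AT3G29970 (at least 43-fold, no count in the control), AT2G17850 (ratio 992, interval 178 to 39200), and AT1G13609, a defensin-like gene (514, interval 176 to 2500). In all 1705 genes rose and 979 fell (747 and 172 at least 2-fold). Against these 2684 calls, 1565, 1593 and 1772 were made without replicates 1, 2 and 3 of the control, 787 and 1224 without replicates 1 and 2 of the iron-free group, and 8204 without its replicate 3.

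Doubly deficient spl7 roots changed few iron genes. AT3G13610 (F6H1) was the only risen gene of 20 for iron uptake (1.28 ± 0.24, adjusted p = 0.00872; 10 over the list alone, camera adjusted p = 8.73e-08, p_est = 0.279). IRT1 read 191, 1290 and 254 CPM in the replicates (578 ± 616). No iron regulator of 23 passed, and 3 rose over the list alone (p_est = 0.226). LAC13 (1.08 ± 0.14) and LAC7 (0.64 ± 0.14) rose and LAC17 fell (-0.72 ± 0.14) among 13 copper proteins (LOO 1 to 2 up, 0 to 1 down). FMO1 (1.83 ± 0.25) and CBP60G (0.88 ± 0.18) rose among 14 salicylate genes (p_est = 0.354), and the jasmonate-induced aminotransferase gene TAT3 fell (-2.31 ± 0.47). Over the list alone 5 of 8 sulfate genes rose (p_est = 0.104) and 5 of 5 xylem genes fell (p_est = 0.226). The cytochrome P450 genes CYP76G1 (4.07) and CYP71B5 (3.62) rose. In all 98 genes rose and 77 fell. Against these 175 calls (W 291, C 783, R 515), 93, 97 and 64 were made without replicates 1, 2 and 3 of the control, and 98, 43 and 82 without those of the doubly deficient group.

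Control roots of spl7 and Col-0 with the same low-copper pretreatment were compared, but genotype is tied to the Ex libraries. FSD1 was at 0.0513 ± 0.0445 CPM in spl7 against 70.8 ± 2 in Col-0 (ratio 1380, interval 382 to 11400). FRO4 was lower by a log2 change of -5.25 ± 0.56, ZIP2 by -3.72 ± 0.26, COPT2 by -2.14 ± 0.61 and YSL2 by -0.96 ± 0.18, and 6 of 9 copper deficiency genes fell (7 over the list alone, camera adjusted p = 1.14e-25, p_est = 2.13e-06). Among 13 copper proteins LAC17 was higher (1.25 ± 0.14) and LAC13 lower (-0.70 ± 0.13), 2 of each (LOO 1 to 2 up, C 5 up). IRT2 (3.06 ± 0.87) and HA2 (AHA2) (0.38 ± 0.11) were higher of 20 uptake genes, the regulator BHLH101 lower (-2.61 ± 0.74), 3 of 23 (LOO 0 to 2), and YSL1 lower (-1.95 ± 0.43), 1 up and 3 down (LOO 1 to 3) of 16 storage genes. Root hair genes rose in 6 of 7 cases (camera adjusted p = 8.72e-12, p_est = 0.0234), with RSL4 at 5.48 ± 1.17 CPM against 1.32 ± 0.473 (2.02 ± 0.32) and PRP3 higher by 1.76 ± 0.25. PRP1, another root hair wall protein gene, went from 0.143 ± 0.13 to 54.8 ± 2.19 CPM (8.53), and the wall-loosening gene XTH13 rose by 6.72.

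Members of the stress lists were also called between the genotypes in control roots. Jasmonate genes were higher in 6 of 19 cases (9 over the list alone, p_est = 0.493), with TAT3 (3.86 ± 0.50), VSP2 (2.54 ± 0.40) and VSP1 (2.35 ± 0.37) higher. Of 10 zinc genes 4 were lower (LOO 2 to 4) and 1 higher (camera adjusted p = 0.00912, p_est = 0.0404): HMA2 (-1.77 ± 0.15), ZIP5 (-0.90 ± 0.24) and ZIP10 (ratio 8.95, interval 2.78 to 45.8) lower and ZIP9 higher (0.90 ± 0.27). AT2G21640 (UPOX), a mitochondrial stress gene, rose by 2.65 ± 0.49, the salicylate conjugation gene PBS3 by 2.11 ± 0.45 (2 up and 1 down of 14) and SAG29 by 2.90 ± 0.71. Of 5 xylem genes 3 rose (C 5; 5 over the list alone, p_est = 0.413), XCP1 by 0.82 ± 0.15. Among 16 clock genes CCA1 was higher (1.03 ± 0.28) and the evening genes ELF4 (-0.71 ± 0.23) and TOC1 (-0.58 ± 0.07) were lower, 2 (LOO 1 to 2) and 3 (C 5). The mitochondrial protein gene AT5G09570 (ratio 233, interval 41.4 to 9260) was higher and CYP76G1 (ratio 97.6, interval 17.2 to 3890) lower in spl7. In all 1382 genes rose and 1330 fell (388 and 238 at least 2-fold). Against these 2712 calls (R 5036), 1249 were made without replicate 2 of the Col-0 control, and 1305 and 1726 without replicates 2 and 3 of the spl7 control.

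Control roots of spl7 were compared after low-copper against high-copper pretreatment. CCH rose (0.47 ± 0.12), the only call of 9 copper deficiency genes. LAC17 (0.58 ± 0.14) and LAC13 (0.51 ± 0.14) rose among 13 copper proteins. Root hair genes rose in 6 of 7 cases (camera adjusted p = 2.19e-15, p_est = 0.0125), PRP3 by 1.63 ± 0.25 and RSL4 by 1.58 ± 0.31, and PRP1 rose by 6.38. Photosynthesis genes rose in 24 of 33 cases (LOO 0 to 30; 32 over the list alone, camera adjusted p = 5.17e-28, p_est = 0.167), with the antenna gene LHCB2.1 at 15.7 ± 9 against 2.46 ± 1.62 CPM (2.67 ± 0.54) and LHCA2 (2.52 ± 0.50). Leaf markers, a check for leaf tissue in roots, rose too, so such tissue is not excluded. Of 8, 5 rose (LOO 0 to 7, C 2, 7 over the list alone, p_est = 0.167), with Rubisco genes RBCS2B (2.32 ± 0.63) and RBCS1A (2.08 ± 0.53). So did 4 of 17 chlorophyll genes (LOO 1 to 5, 7 over the list alone, p_est = 0.167), with CRD1 (2.26 ± 0.39), and plastocyanin DRT112 (PETE2) (1.96 ± 0.53). BGL2 (PR2) (3.2 ± 0.86), ALD1 (1.73 ± 0.44) and FMO1 (1.39 ± 0.25) rose with 5 of 14 salicylate genes (LOO 1 to 6; 8 over the list alone, p_est = 0.167), and LOX2 (2.57 ± 0.64) and VSP2 (2.15 ± 0.39) with 3 of 19 jasmonate genes (W 5, p_est = 0.465). The morning clock genes LHY (1.06 ± 0.21) and CCA1 (1.02 ± 0.28) rose (LOO 1 to 2) and 2 others of 16 fell. The lipid transfer gene LTP4 (ratio 276, interval 49 to 10900) and the dehydrin gene RAB18 (124, interval 33.9 to 1030) rose. In all 608 genes rose and 284 fell (311 and 55 at least 2-fold). Against these 892 calls (C 1356, R 2245), 232 and 360 were made without replicates 1 and 2 of the high-copper control, and 502 and 507 without replicates 1 and 2 of the low-copper control.

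**Figure D2:**
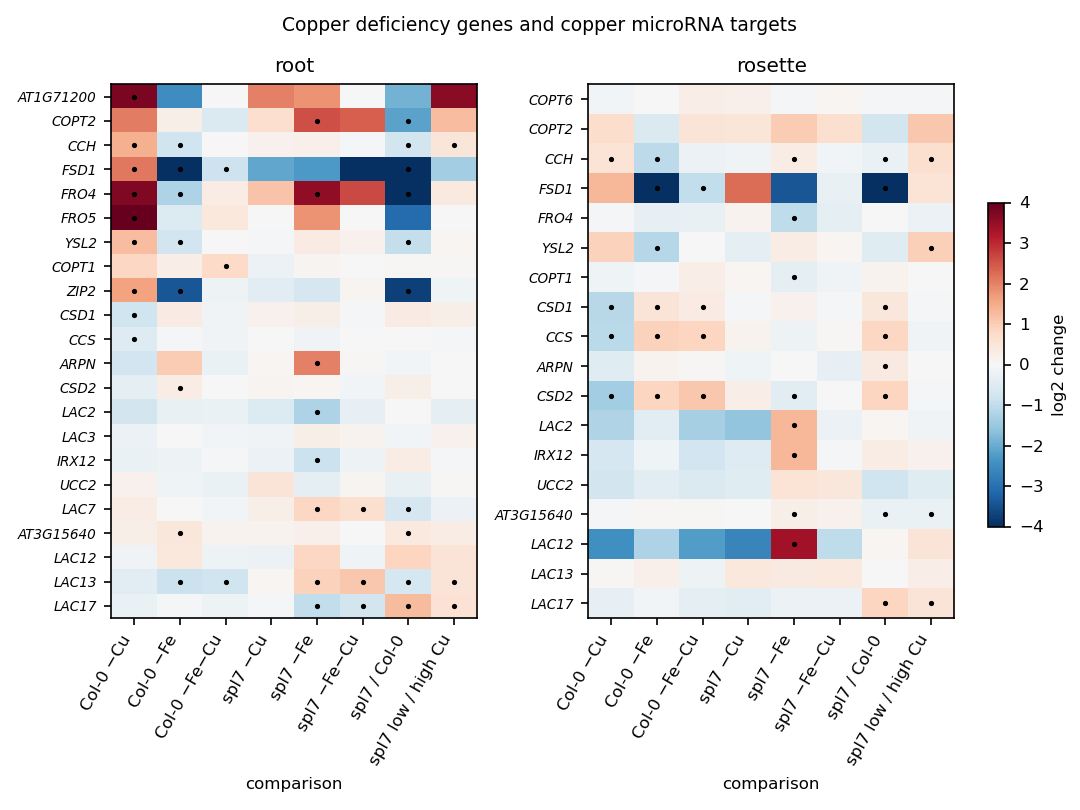
Log2 changes of copper genes in each comparison, clipped at 4 in either direction, with dots at an adjusted p below 0.05. Fitted values of groups without counts depend on the prior of the fit.

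Whether the root responses differed between genotypes was tested as interactions, the log2 change in spl7 less that in Col-0, whose pretreatments also differ. A value above 0 is a smaller fall as well as a larger rise. For copper deficiency 9 genes differed (W 128, C 24, R 173). ZIP2 (-2.07 ± 0.38, adjusted p = 0.0433), CCH (-1.25 ± 0.16, adjusted p = 0.00231), the bHLH gene AT4G28790 (-2.58), OFP1 (-1.36) and AT3G42806.1 (-0.98) were below 0, and CSD1 (0.97 ± 0.17, adjusted p = 0.0417), TCH3 (1.73), AT1G78830 (1.34) and NSP3 (1.05) above 0. The rises of ZIP2 and CCH and the fall of CSD1 in Col-0 stood against -0.46, 0.16 and 0.17 in spl7. Of 9 copper deficiency genes 2 differed (5 over the list alone, camera adjusted p = 3.59e-10, p_est = 0.000517). Without replicate 1 of the Col-0 control 20 genes differed, without replicates 1 and 3 of copper-free Col-0 363 and 5, without replicates 1 and 3 of the spl7 control 5 and 17, and without replicate 3 of copper-free spl7 5.

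For iron deficiency 829 genes were above and 607 below 0 in roots (423 and 239 by at least 2-fold). Copper deficiency genes, which fell in Col-0, held FRO4 (4.80 ± 0.80), ZIP2 (2.77 ± 0.41), YSL2 (1.12 ± 0.26) and CCH (1.01 ± 0.16) above 0, 4 of 9 (5 over the list alone, p_est = 0.00584). LAC13, down in Col-0 and up in spl7, was above 0 (1.80 ± 0.19) and LAC17 below (-0.93 ± 0.20). OPT3, which rose in spl7, was above 0 (3.21 ± 0.84), 4 of 23 iron regulators (LOO 0 to 9, C 0; 8 over the list alone, p_est = 0.261), and AT1G21140 (VTL1) (-3.11 ± 0.93) and FER1 (-2.74 ± 0.65), which fell in spl7, were below 0, 5 and 1 above of 16 storage genes (LOO 4 to 10 below, C 2, p_est = 0.234). Salicylate genes were above 0 in 5 of 14 cases (p_est = 0.0265): CBP60G (2.34 ± 0.26) and SARD1 (2.30 ± 0.24), which fell in Col-0 and rose in spl7, and WRKY70 (2.26 ± 0.35), at -2.33 in Col-0 and -0.07 in spl7. Sulfate genes were in 4 of 8 (LOO 2 to 5, C 2, p_est = 0.0241), SDI1 (listed as ATSDI1) by 2.28 ± 0.43, and STZ (ZAT10) by 2.64 ± 0.46 among 4 of 12 oxidative stress genes (LOO 2 to 7, C 1). Root markers were below 0 in 4 of 9 cases (LOO 2 to 7, C 0, p_est = 0.0172). Against the 1436 calls (C 300, 222 above and 78 below), 647 were made without replicate 2 of the Col-0 control, 719 without replicate 2 of iron-free Col-0, 890 without replicate 2 of the spl7 control, and 760 and 3717 without replicates 1 and 3 of iron-free spl7.

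For the doubly deficient treatment 246 genes were above and 55 below 0 in roots. Sulfate genes were above 0 in 2 of 8 cases (7 over the list alone, p_est = 0.0191), APR3 by 1.45 ± 0.23. The iron regulators BHLH101 (3.68 ± 0.86) and bHLH39 (3.60 ± 0.91) were above 0, 2 of 23 (8 over the list alone, p_est = 0.179), as was AT3G13610 (F6H1) (1.59 ± 0.34), 1 of 20 uptake genes (12 over the list alone, camera adjusted p = 1.08e-09, p_est = 0.211). CBP60G (2.25 ± 0.26) was among 3 of 14 salicylate genes (C 6, p_est = 0.0544). Against the 301 calls (W 557, C 1835, R 1264), 128 were made without replicate 2 of the Col-0 control, 153, 169 and 136 without replicates 1, 2 and 3 of doubly deficient Col-0, 129 and 165 without replicates 1 and 2 of the spl7 control, and 179, 170 and 169 without replicates 1, 2 and 3 of doubly deficient spl7.

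In Col-0 roots the doubly deficient group departed from the sum of the single deficiencies in 591 genes, 295 above and 296 below it. FSD1 was above the sum (3.16 ± 0.36, adjusted p = 8.49e-05), as was ZIP2 (1.60 ± 0.32), whereas COPT2 (-2.84 ± 0.74), FRO4 (-2.13 ± 0.44) and CCH (-0.64 ± 0.16) were below it, 2 and 3 (LOO 1 to 3) of 9 copper deficiency genes. The citrate exporter gene FRD3 (-2.62 ± 0.72) was below the sum, the only call of 20 uptake genes (5 below and 1 above over the list alone). Clock genes departed in 11 of 16 cases, 8 above and 3 below (12 and 3 over the list alone, p_est = 0.229): PRR9 (2.99 ± 0.31), LNK2 (listed as AT3G54500, 2.18 ± 0.35), CCA1 (2.09 ± 0.44) and LHY (2.01 ± 0.31). Against the 591 calls (W 1135, C 2183, R 2985), 311 were made without replicate 2 of the control, 1916, 254 and 341 without replicates 1, 2 and 3 of the copper-free group, 296 and 304 without replicates 2 and 3 of the iron-free group, and 340, 245 and 315 without replicates 1, 2 and 3 of the doubly deficient group.

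**Figure D3:**
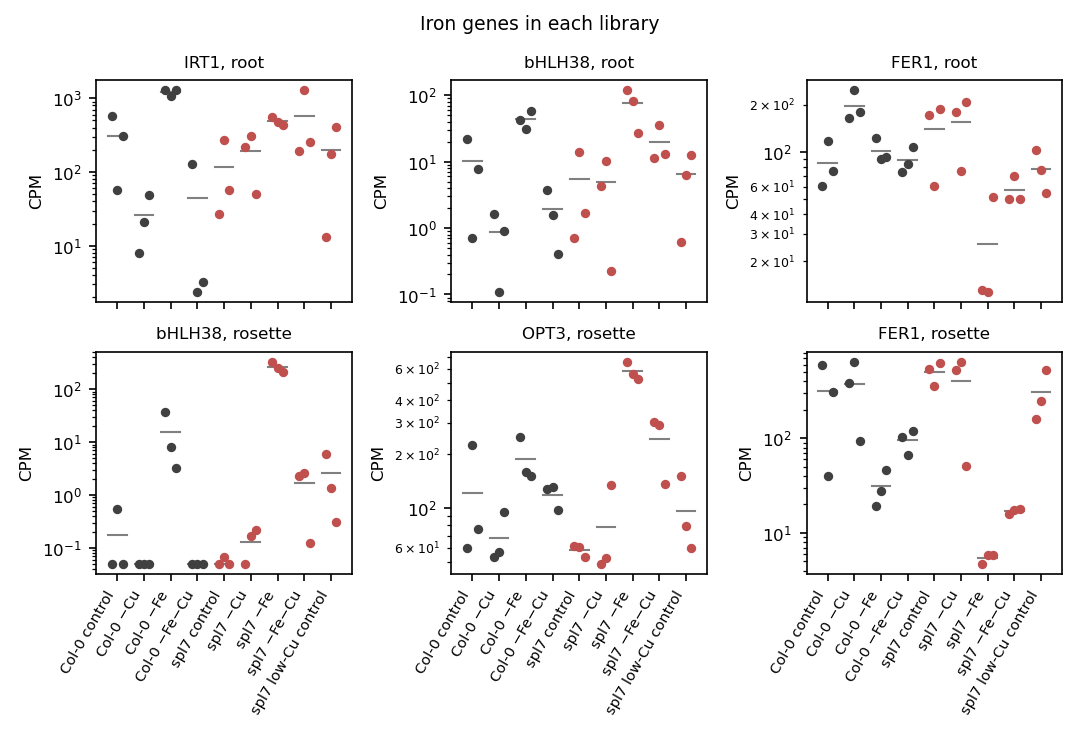
Levels of iron genes in single root and rosette libraries of Col-0 (black) and spl7 (red), with grey lines at group means and values under 0.05 CPM drawn at 0.05.

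In Col-0 rosettes, copper deficiency changed 4 genes (W 37). CSD2, the plastid copper/zinc superoxide dismutase, fell from 457 ± 88.8 to 174 ± 12.2 CPM (-1.40 ± 0.13, adjusted p = 1e-06), CSD1 from 198 ± 20.9 to 92.2 ± 9.77 CPM (-1.1 ± 0.08, adjusted p = 3.95e-08) and CCS from 93.5 ± 13.5 to 43.9 ± 2.99 CPM (-1.09 ± 0.10, adjusted p = 1e-06). CCH rose from 120 ± 7.75 to 175 ± 3.55 CPM (0.54 ± 0.08, adjusted p = 0.00246). FSD1 was at 222 ± 69.7 CPM with copper and 563 ± 24.5 without. Of 11 microRNA-targeted copper proteins 3 fell (7 over the list alone, camera adjusted p = 1.55e-30, p_est = 1.4e-07), and of 7 copper deficiency genes 1 rose (3 over the list alone, camera adjusted p = 0.00081, p_est = 0.00753). At an unadjusted p below 0.05 there were 1718 genes.

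Iron deficiency in Col-0 rosettes turned the same copper genes the other way. CCS rose to 177 ± 11.8 CPM (0.92 ± 0.10), CSD2 to 823 ± 115 (0.85 ± 0.13) and CSD1 to 280 ± 12.3 (0.50 ± 0.08), 3 of 11 copper proteins (p_est = 0.0213). FSD1 fell to 4.93 ± 1.79 CPM (-5.47 ± 0.37, adjusted p = 1.99e-09), CCH to 57.8 ± 2.07 (-1.05 ± 0.08) and YSL2 by -1.14 ± 0.25, 3 of 7 copper deficiency genes (p_est = 1.78e-05). HMA5 rose by 0.94 ± 0.15. Iron regulators rose in 4 of 23 cases (LOO 3 to 9, C 1; 9 over the list alone, camera adjusted p = 4.44e-09, p_est = 0.191): bHLH38 (6.62 ± 1.27, adjusted p = 0.00595), bHLH39 (ratio 102, interval 27.8 to 845), both bHLH activators of the response, AT1G74770 (BTSL1) (3.87 ± 0.48) and bHLH34 (0.45 ± 0.09). Storage genes fell in 8 of 19 cases (LOO 2 to 11, C 1; 14 over the list alone, camera adjusted p = 1.01e-10, p_est = 0.0634), among them FER1 from 315 ± 279 to 31.4 ± 13.9 CPM (-3.31 ± 0.80), the nicotianamine synthase gene NAS3 (-3.2 ± 0.55) and the iron-sulfur protein gene NEET (-1.74 ± 0.40). PSAN, a photosystem I subunit, fell by 0.88 ± 0.19 with 3 of 33 photosynthesis genes (LOO 0 to 6, C 0, W 18; 29 over the list alone, camera adjusted p = 1.37e-22, p_est = 0.191). The salicylate synthase gene EDS16 (ICS1) rose (0.88 ± 0.17), the ethylene synthesis gene ACS6 fell (-1.70 ± 0.44), and the clock genes RVE8 (0.87 ± 0.20) and CCA1 (0.66 ± 0.16) rose, 2 of 16 (p_est = 0.476). AT2G18193, an ATPase gene (5.14, adjusted p = 6.69e-11) and the defensin-like gene AT1G13609 (4.70) also rose. In all 304 genes rose and 178 fell (88 and 56 at least 2-fold). Against these 482 calls (C 158, 133 up and 25 down), 178 were made without replicate 1 of the control, and 262 and 188 without replicates 1 and 2 of the iron-free group.

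Doubly deficient Col-0 rosettes were compared with the control. CSD2 rose to 973 ± 86 CPM (1.09 ± 0.13), CCS to 170 ± 14.5 (0.87 ± 0.10) and CSD1 to 250 ± 11.1 (0.34 ± 0.08), although copper was absent, and 3 of 11 copper proteins rose (3 and 3 lower over the list alone, p_est = 0.432). FSD1 fell to 111 ± 39.3 CPM (-1 ± 0.28, adjusted p = 0.0318), the only call of 7 copper deficiency genes (1 higher and 2 lower over the list alone), and the plastid copper pump gene PAA1 rose by 0.27 ± 0.08. Of 23 iron regulators bHLH34 rose (0.49 ± 0.09), of 14 uptake genes NAS1 (0.60 ± 0.15), and of 19 storage genes CAT2 rose (0.91 ± 0.19) and YSL3 fell (-0.52 ± 0.14). Clock genes changed in 15 of 16 cases, 8 up and 7 down (9 and 7 over the list alone, p_est = 0.535): CCA1 from 15.6 ± 0.708 to 47.1 ± 2.86 CPM (1.59 ± 0.16), RVE8 (1.45 ± 0.19) and ELF4 from 29.6 ± 2.71 to 9.05 ± 0.458 CPM (-1.71 ± 0.17). Chlorophyll genes rose in 7 of 18 cases (LOO 3 to 8) and 1 fell (10 and 1 over the list alone, p_est = 0.432), with CH1 (CAO), which makes chlorophyll b (0.80 ± 0.08), HEMA1 (0.72 ± 0.21) and GUN5 (0.64 ± 0.16) up and the ferrochelatase gene FC1 down (-0.75 ± 0.17). Of 33 photosynthesis genes 3 rose (LOO 1 to 5, W 5; 5 over the list alone, p_est = 0.535), the ferredoxin gene FD1 by 0.46 ± 0.09, and of 8 leaf markers 4 rose (LOO 1 to 5; 7 over the list alone, p_est = 0.387), RCA, the Rubisco activase gene, by 0.73 ± 0.11.

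Members of the stress lists were among the falls in doubly deficient Col-0 rosettes. STZ (ZAT10), a zinc finger gene of abiotic stress, was at 19.1 ± 19.4 CPM in the control (41.4 in replicate 1, 6.25 and 9.6 in the others) and 1.83 ± 0.251 without both metals (-3.39 ± 0.72), and BAP1, a cell death inhibitor, fell by 3.06 ± 0.62, among 4 of 10 oxidative stress genes (LOO 1 to 4, C 2, p_est = 0.432). SARD1 (-1.68 ± 0.23) and WRKY70 (-1.50 ± 0.32) were among 3 fallen of 15 salicylate genes (p_est = 0.535), and the sulfate reductase gene APR2 rose by 1.04 ± 0.11. RRTF1, a redox-responsive factor gene (ratio 436, interval 77.9 to 17300) and the dwarfing factor gene DDF1 (232, interval 41.3 to 9210) were far lower. In all 793 genes rose and 762 fell (51 and 290 at least 2-fold). Against these 1555 calls, 700 and 986 were made without replicates 1 and 3 of the control, and 863 and 843 without those of the doubly deficient group.

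**Figure D4:**
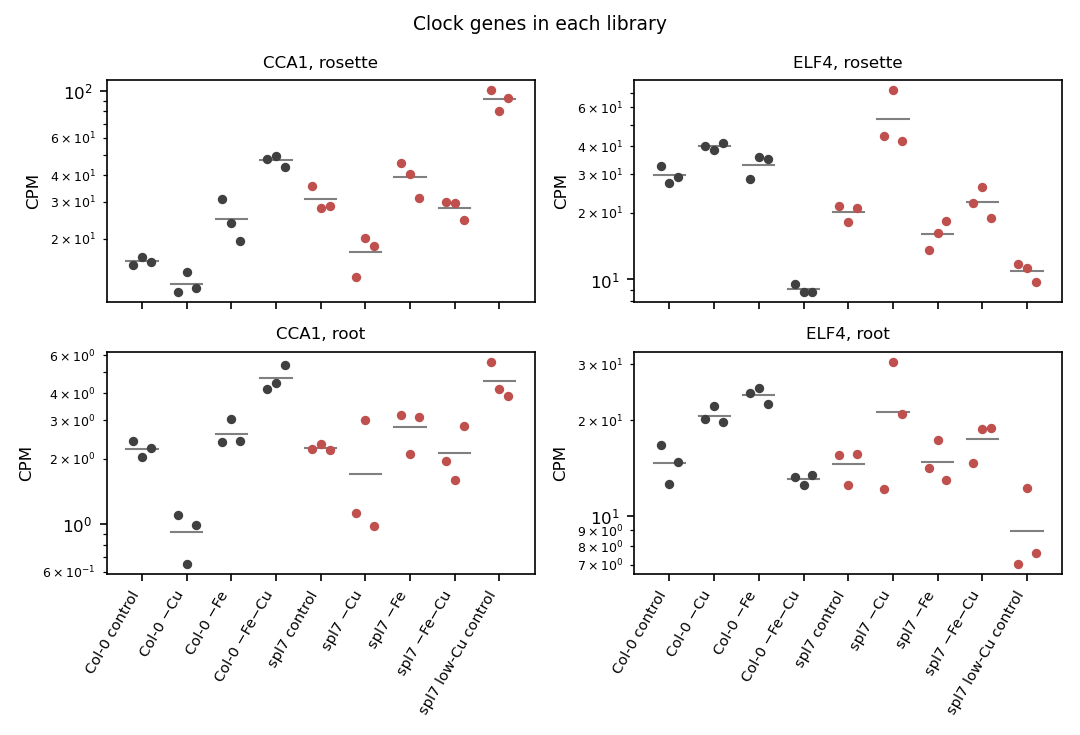
Levels of the clock genes CCA1 and ELF4 in single rosette and root libraries, with grey lines at group means.

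Copper deficiency in spl7 rosettes called more members of the clock list than of any other. ELF4 rose by 1.38 ± 0.16 and TOC1 by 0.84 ± 0.13, while RVE8 (-1.13 ± 0.21) and CCA1 (-0.83 ± 0.16) fell, 4 up and 4 down (LOO 2 to 4) of 16 (7 and 6 over the list alone, p_est = 0.744). The cold and clock gene COR27 (2.08) rose. AT2G25625 (ratio 30.1, interval 7.94 to 255), SAG29 (-2.43 ± 0.60) and PRP2 (-1.52) fell. CSD1 was 276 ± 4.47 CPM with copper and 266 ± 25 without, and no copper list member passed. In all 140 genes rose and 85 fell. Against these 225 calls, 74, 58 and 149 were made without replicates 1, 2 and 3 of the control, and 120 and 949 without replicates 2 and 3 of the copper-free group. A fit of only the compared groups called 0 with edgeR (1718 genes at an unadjusted p below 0.05), and W was 491.

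Iron deficiency in spl7 rosettes changed 20 of 23 iron regulators. BHLH100 had no count in the control and 191 ± 34 CPM without iron (at least 868-fold), and the related regulators bHLH38 (ratio 11000, interval 1970 to 433000) and bHLH39 (4320, interval 774 to 171000) and the peptide genes AT1G47395 (IMA2) (5680, interval 1020 to 224000) and AT1G47400 (IMA1) (2230, interval 618 to 18400) came on with it. OPT3 rose from 58.6 ± 4.68 to 581 ± 67.5 CPM. Of these regulators 18 rose and 2 fell (LOO 0 to 2 down, C 1 down, camera adjusted p = 5.38e-20, p_est = 0.0351). Storage genes fell in 14 of 19 cases and 1 rose (camera adjusted p = 5.4e-18, p_est = 0.0244): FER1 from 505 ± 135 to 5.44 ± 0.622 CPM (-6.54 ± 0.97), NEET from 74 ± 5.87 to 1.19 ± 0.652 CPM (-5.93 ± 0.57), NAS3 (-4.37 ± 0.56), FER4 (-4.36 ± 0.49) and the plastid rubredoxin gene ENH1 (-4.05 ± 0.36). Of 14 uptake genes 5 rose (LOO 3 to 5, camera adjusted p = 0.0062, p_est = 0.0719), FRD3 (2.86 ± 0.69), IRT1 (2.72 ± 0.37) and FRO2 (1.41 ± 0.24). All 33 photosynthesis genes fell (camera adjusted p = 9.43e-38, p_est = 0.0719), the ferredoxin gene FED A (FD2) from 2370 ± 181 to 377 ± 82 CPM (-2.65 ± 0.26) and PSAN from 2340 ± 220 to 434 ± 127 CPM (-2.43 ± 0.20). Of 18 chlorophyll genes 14 fell (camera adjusted p = 1.41e-11, p_est = 0.0989), HEMA1 from 636 ± 74.8 to 61.9 ± 15.3 CPM (-3.36 ± 0.24) and GUN5 by -1.63 ± 0.16, and 7 of 8 leaf markers fell (p_est = 0.156).

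In iron-free spl7 rosettes CCH and CSD2, not HMA5, went against Col-0. FRO4 (-1.01 ± 0.21) and COPT1 (-0.36 ± 0.09) fell and CCH rose (0.29 ± 0.08), 1 and 2 of 7. CSD2 fell (-0.44 ± 0.13), and 4 copper proteins of 11 rose, with the laccase genes LAC12 (3.36 ± 0.76), LAC2 (1.34 ± 0.44) and IRX12 (LAC4) (1.34 ± 0.28), which lignify walls. HMA5 rose (0.71 ± 0.16) and plastocyanin DRT112 (PETE2) (-0.53 ± 0.12) and the thylakoid copper pump gene PAA2 (-0.50 ± 0.11) fell, 1 and 3 of 8. Of 5 xylem genes 3 rose (p_est = 0.32), IRX3 by 2.16 ± 0.33. Zinc genes rose in 4 of 7 cases (p_est = 0.0727), IRT3 by 1.14 ± 0.29 and ZIP4 by 1.06 ± 0.15, and phosphate genes in 5 of 9 (LOO 3 to 5, p_est = 0.0989), PS2, a phosphatase gene, by 1.2 ± 0.34. Salicylate genes rose in 7 of 15 cases (p_est = 0.323), PR1 by 3.58 ± 0.88, glucosinolate genes in 7 of 15 (8 over the list alone, p_est = 0.336), IMS2 (MAM3) by 1.44 ± 0.18, and anthocyanin genes in 4 of 8 (LOO 0 to 5, p_est = 0.411), UF3GT by 1.71 ± 0.47. Senescence genes fell in 5 of 8 cases (LOO 2 to 4; 6 over the list alone, p_est = 0.0989), all called ones tied to chlorophyll breakdown except the regulator NAC6 (NAC092), and NYC1 by -3.00 ± 0.26. The catalase genes CAT1 (-1.81 ± 0.18) and CAT3 (-1.55 ± 0.15) fell and AT2G21640 (UPOX) rose (1.27 ± 0.20), 2 up (LOO 1 to 2) and 3 down of 10 oxidative stress genes, and 4 clock genes rose and 6 fell of 16. AT1G13609 had no count in the control (at least 1330-fold). The pyruvate kinase-like gene AT3G49160 (-7.06), the desiccation protein gene LEA7 (-6.92) and AT2G42560, of the same kind (ratio 191, interval 33.7 to 7570), fell. In all 2515 genes rose and 2967 fell (466 and 305 at least 2-fold). Against these 5482 calls, 3504 were made without replicate 1 of the iron-free group.

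Doubly deficient spl7 rosettes also changed iron genes. AT1G47400 (IMA1) had a ratio of 149 (interval 40.9 to 1240), AT2G30766 (IMA3) rose by 7.03 ± 1.82, BHLH101 by 4.56 ± 1.09, OPT3 by 2.05 ± 0.45 and BTS, a ubiquitin ligase gene that senses iron, by 1.67 ± 0.39. Of 23 iron regulators 6 rose (LOO 0 to 12, C 9, W 11; 13 over the list alone, camera adjusted p = 1.05e-11, p_est = 0.139). Storage genes fell in 12 of 19 cases (LOO 3 to 10; 13 and 1 higher over the list alone, camera adjusted p = 6.25e-16, p_est = 0.0185), FER1 to 17.1 ± 1.13 CPM (-4.88 ± 0.87), NAS3 (-3.14 ± 0.51) and FER3 (-2.05 ± 0.47). Senescence genes fell in 5 of 8 cases (LOO 0 to 3; 7 over the list alone, camera adjusted p = 1.78e-10, p_est = 0.00879), SAG29 by -2.40 ± 0.60 and NYC1 by -1.07 ± 0.24. ZIP4 (0.60 ± 0.16) and ZIP1 (0.57 ± 0.14) rose, 2 of 7 zinc genes (p_est = 0.146), and WRKY70 rose by 1.58 ± 0.32. AT2G42560 (at least 16.9-fold) and LEA7 (-7.42) fell. In all 180 genes rose and 242 fell (54 and 78 at least 2-fold). Against these 422 calls (C 807), 42 and 278 were made without replicates 1 and 2 of the control, and 115, 113 and 254 without replicates 1, 2 and 3 of the doubly deficient group.

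Control rosettes of spl7 and Col-0 with the same pretreatment differed in 8453 genes, 4131 higher and 4322 lower in spl7 (895 and 697 at least 2-fold). FSD1 was at 0.425 ± 0.188 CPM in spl7 (-8.98 ± 0.52, adjusted p = 1e-10), and CCH was lower by -0.26 ± 0.08, 2 of 7 copper deficiency genes. CSD2 was higher at 830 ± 31.4 CPM (0.86 ± 0.13), with LAC17 (0.86 ± 0.13), CCS (0.83 ± 0.10) and CSD1 (0.44 ± 0.08), 5 up and 1 down of 11 (p_est = 0.302), and PAA2 was lower (-0.53 ± 0.11). Anthocyanin genes were higher in 8 of 8 cases (camera adjusted p = 1.36e-07, p_est = 0.302): DFR at 39.5 ± 15.9 against 2.58 ± 1.28 CPM (3.97 ± 0.49), UF3GT (3.84 ± 0.50) and LDOX (3.00 ± 0.43), all enzymes of the pigment pathway. Glucosinolate genes were higher in 13 of 15 cases (camera adjusted p = 3.6e-06, p_est = 0.302), BCAT4 by 0.87 ± 0.12 and MAM1 by 0.78 ± 0.10. Senescence genes were higher in 6 of 8 cases (p_est = 0.302), SAG29 by 5.44 ± 0.50. Clock genes differed in 14 of 16 cases, 9 up and 5 down (p_est = 0.302), with CCA1 at 91.5 ± 10.3 against 15.6 ± 0.708 CPM (2.55 ± 0.16) and RVE8 (2.48 ± 0.19) higher.

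Iron and stress genes differed as well between these control rosettes. FRD3 (2.32 ± 0.72), FRO2 (1.94 ± 0.24) and AT3G13610 (F6H1) (1.79 ± 0.45) were higher and HA2 (AHA2) lower (-0.73 ± 0.09), 5 and 2 of 14 uptake genes. AT1G74770 (BTSL1) (1.73 ± 0.58) and the vacuolar iron exporter gene NRAMP4 (0.97 ± 0.23) were higher, 5 of 23 regulators (LOO 3 to 8). CAT2 was higher (1.40 ± 0.19) and FER3 lower (-1.44 ± 0.45), 1 and 4 of 19 storage genes. VSP2 was higher (3.07 ± 0.31) and PDF1.2 lower (-3.06 ± 1.1), 8 and 2 (LOO 0 to 3, C 1) of 21 jasmonate genes. PR1 (4.14 ± 0.99) and BGL2 (PR2) (2.76 ± 0.60) were higher, 5 up and 2 down of 15 salicylate genes (LOO 3 to 6 and 1 to 2). ACS2 (2.65 ± 0.49) was higher and ACS6 lower (-2.43 ± 0.48), 3 and 3 of 9 ethylene genes. BAP1 (-2.46 ± 0.58) and STZ (ZAT10) (-2.21 ± 0.65) were lower, 2 up and 5 down (LOO 2 to 5, C 3) of 10 oxidative stress genes, as was the etiolation gene PORA (-1.59 ± 0.22), 2 up and 9 down of 18 chlorophyll genes. Desiccation genes rose, AT2G42560 (at least 151-fold) and LEA7 from 0.284 ± 0.262 to 264 ± 133 CPM (9.87). Leaving out any replicate kept the number of calls between 7104 and 7689.

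Within spl7 rosettes, low-copper against high-copper pretreatment changed 4786 genes, 2391 up and 2395 down (433 and 245 at least 2-fold). YSL2 (0.96 ± 0.27) and CCH (0.64 ± 0.08) rose, 2 of 7 copper deficiency genes. Anthocyanin genes rose in 8 of 8 cases (camera adjusted p = 5.63e-09, p_est = 0.287), DFR by 3.09 ± 0.46 from 4.67 ± 0.324 CPM, and glucosinolate genes in 9 of 15 (12 over the list alone, camera adjusted p = 5.01e-06, p_est = 0.409), BCAT4 by 0.71 ± 0.12. Clock genes changed in 12 of 16 cases, 8 up and 4 down (p_est = 0.409), RVE8 by 1.64 ± 0.18 and CCA1 by 1.57 ± 0.15. AT2G30766 (IMA3) (6.10 ± 2.01) and BHLH101 (3.48 ± 1.23) rose among 5 of 23 iron regulators (LOO 2 to 7, W 10, camera adjusted p = 0.00128, p_est = 0.58), FRD3 (2.24 ± 0.73) and FRO2 (1.70 ± 0.24) among 5 of 14 uptake genes (LOO 2 to 5), 2 of which fell. Of 19 storage genes AT3G25190 (VTL5) rose (2.30 ± 0.55) and FER3 fell (-1.54 ± 0.46) with 1 other (LOO 0 to 2, C 5, W 1). Sulfate genes fell in 5 of 9 cases (LOO 3 to 5, p_est = 0.488), the sulfur shortage gene LSU1 by -1.51 ± 0.39. SAG29 (3.24 ± 0.41) and VSP2 (1.94 ± 0.29) rose, and PORA (-0.92 ± 0.22) and RBCS1B (-0.83 ± 0.15) fell, with 4 of 8 leaf markers lower (LOO 2 to 4). Without replicate 2 of the high-copper control 3080 genes were called.

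**Figure D5:**
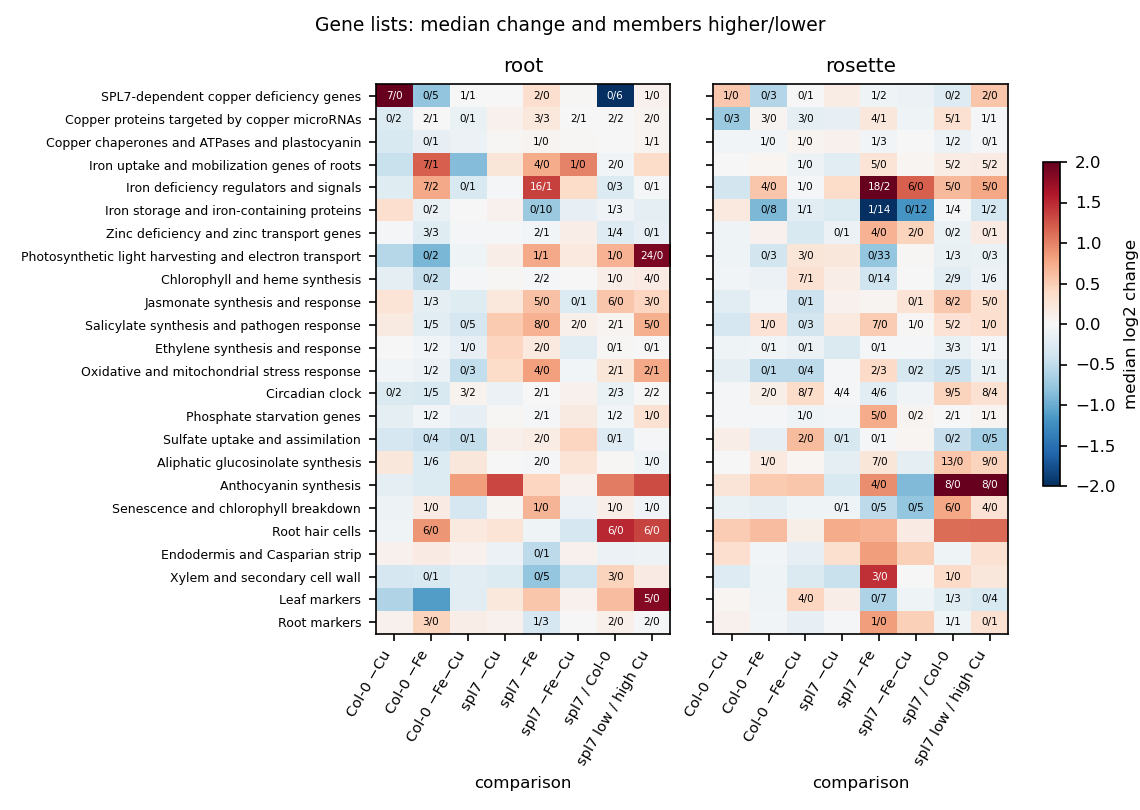
Median log2 change of each gene list per comparison, clipped at 2 in either direction, with the numbers of members called higher and lower.

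Interactions in rosettes asked whether the genotypes, with their pretreatments, responded differently. For copper deficiency 6 genes differed (W 70): CSD2 (1.65 ± 0.18, adjusted p = 3.41e-05), CCS (1.24 ± 0.14) and CSD1 (1.05 ± 0.11), which fell in Col-0, CCH (-0.67 ± 0.11), AT4G33980 (1.76) and the flowering regulator COL9 (1.17). The copper protein list differed in 3 of 11 members (camera adjusted p = 8.18e-10, p_est = 0.000561). Without replicates 1 and 3 of the Col-0 control 3 and 14 genes differed, without replicate 2 of copper-free Col-0 3, without replicates 1 and 2 of the spl7 control 3 and 3, and without replicate 3 of copper-free spl7 27.

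For iron deficiency 680 genes were above and 1013 below 0 in rosettes (245 and 164 by at least 2-fold). CCH (1.35 ± 0.11) and YSL2 (1.46 ± 0.38), which fell in Col-0, were above 0, and CSD2 (-1.29 ± 0.18) and CCS (-1.13 ± 0.14), which rose in Col-0, below. BTS (2.78 ± 0.54) and OPT3 (2.67 ± 0.62), which rose in spl7, were above 0, 12 of 23 iron regulators, and 1 below (13 and 1 over the list alone, camera adjusted p = 8.59e-12, p_est = 0.132). NEET (-4.18 ± 0.74) and ENH1 (-3.08 ± 0.46), which fell in spl7, were below 0, 8 of 19 storage genes (10 and 1 above over the list alone, p_est = 0.132). HEMA1 (-2.76 ± 0.31), GUN5 (-1.48 ± 0.22), FED A (FD2) (-1.81 ± 0.35) and PSAN (-1.55 ± 0.27), which fell in spl7, were below 0, the latter pair with 6 of 33 photosynthesis genes (LOO 3 to 9, W 11; 16 over the list alone, camera adjusted p = 4.76e-12, p_est = 0.26). Against the 1693 calls, 1020 were made without replicate 3 of the Col-0 control, 947 and 976 without replicates 2 and 3 of iron-free Col-0, 942 and 1020 without replicates 1 and 3 of the spl7 control, and 893 without replicate 1 of iron-free spl7.

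For the doubly deficient treatment 776 genes were above and 884 below 0 in rosettes (352 and 172 by at least 2-fold). CSD2 (-1.08 ± 0.18), CCS (-0.80 ± 0.14) and CSD1 (-0.41 ± 0.11), raised in Col-0, were below 0. NAS3 (-2.75 ± 0.68), NEET (-2.12 ± 0.54) and CAT2 (-2.09 ± 0.27), which fell in spl7, were below 0, 6 of 19 storage genes (LOO 5 to 10; 10 and 1 above over the list alone, p_est = 0.326), and OPT3 (2.08 ± 0.62) and BTS (1.84 ± 0.54), which rose in spl7, were above 0, 4 of 23 regulators (LOO 0 to 8, C 8, W 10) and 1 below (9 and 1 over the list alone, p_est = 0.552). Clock genes differed in 10 of 16 cases, ELF4 by 1.86 ± 0.23 and CCA1 by -1.73 ± 0.23. WRKY70 (3.08 ± 0.45) and SARD1 (2.43 ± 0.32) were above 0, and HEMA1 below (-1.36 ± 0.30). Against the 1660 calls, 1005 were made without replicate 1 of doubly deficient spl7.

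In Col-0 rosettes the doubly deficient group departed from the sum of the single deficiencies in 905 genes, 529 above and 376 below it. CSD2 (1.64 ± 0.18), CCS (1.04 ± 0.14) and CSD1 (0.94 ± 0.11) were above the sum, 3 of 11 copper proteins (camera adjusted p = 9.53e-06, p_est = 0.0143), as was FSD1 (3.13 ± 0.45, adjusted p = 0.000141). Photosynthesis genes were above it in 24 of 33 cases (LOO 10 to 29; 32 over the list alone, camera adjusted p = 1.38e-33, p_est = 0.119), PSAN by 1.18 ± 0.27 and CAB2 (LHCB1.1) by 1.02 ± 0.19, and chlorophyll genes in 5 of 18 (W 8; 9 over the list alone, p_est = 0.164), HEMA1 by 1.41 ± 0.30. NAS3 (2.88 ± 0.72) was above the sum, and IRT1 (-3.46 ± 0.71) below it. Clock genes departed in 12 of 16 cases, ELF4 by -2.30 ± 0.23 and PRR9 by 1.88 ± 0.16. Against the 905 calls, 576 were made without replicate 2 of the copper-free group, 515 without replicate 2 of the iron-free group and 478 without replicate 2 of the doubly deficient group.

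Genes shared between comparisons were counted to ask how the metal responses relate. In Col-0 roots 6 genes called under both single deficiencies went in opposite directions (CCH, FSD1, FRO4, YSL2, ZIP2 and AT5G14550) and 2 in the same direction (PRR9 and AT4G30350), where 1.54 opposite, 0.994 shared rises and 0.521 shared falls would come from unrelated sets. The log2 changes of all genes had a correlation of 0.12 and a covariance of 0.022, against 0.49 and 0.031 in simulated data with the same shared controls and no change. In Col-0 rosettes all 4 copper-responsive genes (CSD1, CCS, CSD2 and CCH) went the opposite way under iron deficiency, where 0.0545 would come from unrelated sets (correlation 0.4, simulated 0.51; covariance 0.047, simulated 0.034). The genotype contrast of controls, which shares the Col-0 controls with copper deficiency, had 0 genes alike and 5 opposite to it in roots (CCH, FSD1, FRO4, YSL2 and ZIP2; 0.988 expected) and 0 and 4 in rosettes (CSD1, CCS, CSD2 and CCH; 0.835 expected), although the correlation over all genes was positive (0.29 in roots, simulated 0.48, and 0.28 in rosettes, simulated 0.5). In spl7 roots 20 genes moved alike without copper and without iron and 2 oppositely. Unrelated sets would give 3.25 shared rises, 0.191 shared falls and 2.2 opposite (correlation 0.5, simulated 0.49, covariance 0.101, simulated 0.032). Simulated data without change cannot show how many came from shared controls. In spl7 rosettes 32 moved in the same direction (14 rises against 17.6 expected, 18 falls against 12.6) and 56 in opposite directions (31.4 expected; covariance 0.047, simulated 0.033). Between genotypes, with no shared controls, iron deficiency gave 284 shared rises (169 expected), 260 shared falls (102 expected) and 135 opposite genes (275 expected) in roots (correlation 0.38), and 118 shared rises (38.2 expected), 86 shared falls (26.4 expected) and 31 opposite genes (67.4 expected) in rosettes (correlation 0.32). The copper-responsive genes of both genotypes were too few for an overlap (0 shared, with at most 0.0252 expected for any direction in either tissue), and the correlation over all genes was -0.07 in roots and 0.03 in rosettes. With 3 control libraries the controls were not divided between the responses.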

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

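The regroupings of libraries (splits) were planned, and every other test in this part was chosen after the result was seen.

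A difference between groups drew attention to all 8 interactions, which test the difference itself. In roots 9 genes (4 higher, 5 lower) differed between genotypes in the copper-free response, 1436 (829 and 607) in the iron-free response and 301 (246 and 55) in the doubly deficient response, and 591 (295 and 296) departed from additivity in Col-0. In rosettes the numbers were 6 (5 and 1), 1693 (680 and 1013), 1660 (776 and 884) and 905 (529 and 376). Genotype and pretreatment are confounded in the genotype interactions.

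Each interaction had 40 splits. The real split included, 2 root splits called at least as many genes as the real 9 (highest other 21). For 1436, 301 and 591 there were 3, 2 and 3 (highest other 7333, 381 and 4414). In rosettes this held for 7 splits against 6 (highest other 190), 5 against 1693 (4120) and 2 against 905 (1003). Only the real split reached 1660 (highest other 602). The same split gave the highest other 381, 4414, 190, 4120 and 1003. Whether such splits keep part of the treatment effects was not tested, so they do not decide on chance.

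Comparisons of 3 against 3 libraries have 10 splits, too few for a share under 0.05. In roots the number of splits at least as large, the real value and the highest other were 2, 15 and 150 for copper-free Col-0, 1, 4165 and 1 for iron-free Col-0, 1, 960 and 1 for doubly deficient Col-0, 1, 43 and 0 for copper-free spl7, 4, 2684 and 4642 for iron-free spl7, 1, 175 and 0 for doubly deficient spl7, 1, 2712 and 0 between genotypes, and 1, 892 and 0 between pretreatments. In rosettes the same splits gave 2, 4 and 86, 1, 482 and 0, 1, 1555 and 0, 1, 225 and 2, 1, 5482 and 0, 1, 422 and 1, 1, 8453 and 2, and 1, 4786 and 0 in the same order. The highest others of 150 and 86 are several times the real number, and that of 4642 is above it, which points to a structure of the samples.

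Replicate 3 of iron-free spl7 roots lay apart from replicates 1 and 2, at a distance (root mean square difference of log2 CPM) of 0.789 from their mean, against 0.313 between replicates 1 and 2. Exchanged labels of 2 root libraries are argued against, since 0 other root libraries lay closer to replicates 1 and 2 than to their own group (2 root libraries with exchanged labels). So is too little depth in replicate 3, with 3 of 26 other root libraries below its 12.28 M counts. No iron deficiency in replicate 3 is argued against as well, since 16 of the 17 iron regulators above all control libraries in replicates 1 and 2 were above them in replicate 3, though at a median log2 difference of -1.45, so a weaker deficiency stays open. That it is 1 Col-0 root library under this label is excluded by its SPL7 level of 25.1 CPM. Still open is 1 library of another spl7 root group under this label. Replicate 3's distance to doubly deficient spl7 roots was 0.87 of the largest within that group, but also 0.93 for the excluded Col-0 control. A plant-to-plant difference or low oxygen in replicates 1 and 2 stays open too, untested.

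In edgeR 0 of 20 iron uptake genes rose in doubly deficient Col-0 roots, against 7 in iron-free ones (2 to 7 with a replicate left out, 15 with only the compared groups, IRT1 and FRO2 not called, p_est = 0.486). Libraries of another Col-0 root group under this label are argued against, because the smallest number of genes called against another Col-0 root group was 960, with 1159 against the copper-free and 1784 against the iron-free group. A rise hidden by the spread of the control libraries is argued against too: with any control library left out, 0 uptake genes were raised in edgeR and the median log2 change was -0.39, -1.09 or -0.99. Missing copper may act on iron uptake, a hypothesis from these same data: 15 of 20 uptake genes were below iron-free roots and 0 above. Only FRD3 departed from additivity, and the genotype interaction called AT3G13610 (F6H1) alone. Weak iron deficiency (no iron regulator rose) and low oxygen, untested, stay open.

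Clock genes shifted between rosette groups. Scaling of the libraries is argued against, since 1 factor per library moves all genes alike and 24 of 61 rosette clock calls went against the more frequent direction of their comparison. Groups harvested at different times of day may explain the shift, as 86.9 percent of the rosette clock calls (53 of 61) had the same direction in roots of the same groups, and an effect of the treatments or genotype on the clock would give this too, so both stay open.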

How the results depend on the processing

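The alternatives fitting only the compared groups and fitting 26 root libraries were chosen after seeing the data, and the others were planned. None of 939 values of named genes was reversed by any alternative. The same call was kept by 933 with DESeq2 size factors, 921 with no filter, 888 with the replicate block, 912 with the DESeq2 Wald test, 725 of 911 with only the compared groups, 307 of 307 with the 26 root libraries and 5511 of 7260 over all leave-one-out fits. The number of genes called stayed within 1.5 times the reported one in 24 of 24 comparisons with DESeq2 size factors, 24 with no filter, 23 with the block, 14 with the Wald test, 13 with the compared groups alone, 0 of 10 with the 26 root libraries and 98 of 192 leave-one-out fits. DESeq2 size factors moved the median gene of a comparison by at most 0.007, too little to test a dependence on scaling. Of 528 list tests, camera called 225 at its preset and 23 with an estimated correlation.

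The DESeq2 Wald test moved the number of called genes in roots to 190 (copper-free Col-0), 1473 (doubly deficient Col-0), 169 (copper-free spl7), 291 (doubly deficient spl7), 128, 557 and 1135 (genotype by copper, genotype by both metals, iron by copper), and in rosettes to 37 (copper-free Col-0), 491 (copper-free spl7) and 70 (genotype by copper). With only the compared groups the root numbers were 2322 (doubly deficient Col-0), 0 (iron-free spl7, edgeR, 2621 genes at an unadjusted p below 0.05), 783 (doubly deficient spl7), 1356 (spl7 pretreatments) and 24, 300, 1835 and 2183 (the interactions), and the rosette numbers 158 (iron-free Col-0), 0 (copper-free spl7, edgeR, 1718 genes at an unadjusted p below 0.05) and 807 (doubly deficient spl7). With 26 root libraries they were 271, 6482 and 2667 for Col-0 without copper, iron and both, 355 and 515 for spl7 without copper and both, 5036 between genotypes, 2245 between pretreatments and 173, 1264 and 2985 for the interactions of genotype by copper, genotype by both metals and iron by copper. For these shifts the cause was not tested. The replicate block moved the root genotype by copper interaction to 5 genes, and the numbers do not pair the libraries (mean correlation of residuals -0.007 for equal and 0.003 for other numbers in roots, 0.003 and -0.002 in rosettes).

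Leave-one-out gave, lowest to highest, in roots of Col-0 11 to 1518 genes without copper (highest without copper-free replicate 1), 1456 to 3945 without iron and 174 to 875 without both (lowest without control replicate 2 for each), in roots of spl7 0 to 57 without copper (lowest without control replicate 1 or 2, edgeR, 1260 and 1270 genes at an unadjusted p below 0.05), 787 to 8204 without iron (replicates 1 and 3) and 43 to 98 without both, 1249 to 2521 between genotypes, 232 to 859 between pretreatments, and 5 to 363, 647 to 3717, 128 to 319 and 245 to 1916 for the interactions. In rosettes it gave 178 to 481 without iron and 700 to 1989 without both in Col-0 (lowest without control replicate 1), 58 to 949, 3504 to 4973 and 42 to 301 without copper, iron and both in spl7, 3080 to 4395 between pretreatments, and 3 to 27, 893 to 1879, 1005 to 1816 and 478 to 958 for the interactions. With a replicate left out the remaining libraries are assumed to vary like the other groups. Depth limits the genes at the floor: a group without counts allows only a lower bound against 3 counts per library. Replicate spread exceeded counting error in all 54 pairs of counts (chi-square per degree of freedom 2.64 to 69.1, median 6.64).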

Other observations

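All tests and the 3 lists here were chosen after seeing the result and values of some members. Members prompting a list were left out of its test. Camera p is unadjusted, so weak evidence.

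Low-oxygen genes were among the largest rises in doubly deficient Col-0 roots. A low-oxygen response in these roots may be a candidate explanation: 5 of the 11 other low-oxygen genes rose, with a median log2 change of 1.84 (camera p = 0.0203 with an estimated correlation). The same list rose in 10 of 11 cases in iron-free spl7 roots (p = 0.034 with an estimated correlation), where the median log2 levels over the Col-0 control were 3.13 and 3.17 in replicates 1 and 2 and 0.30 in replicate 3, and replicate 2 of copper-free spl7 roots stood at 2.03. Uneven levels between replicates of 1 treatment could reflect the aeration of single containers, which the labels do not identify. The labels mention constant aeration. In iron-free spl7 rosettes 7 of 11 rose and 1 fell (camera p = 0.139 with an estimated correlation).

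Desiccation genes were among the largest rises in control rosettes of spl7 against Col-0, RAB18 with 1250 ± 431 against 26.6 ± 4.07 CPM (SD, n = 3). A response to abscisic acid or drying in these rosettes may explain them: 14 of 18 other genes rose, with a median log2 change of 1.41 (camera p = 0.0445 with an estimated correlation). Between the pretreatments of spl7 13 of 18 rose (camera p = 0.0526 with an estimated correlation), and in doubly deficient spl7 rosettes 10 fell (camera p = 0.0305 with an estimated correlation). RAB18 was uneven in the high-copper control of spl7 (237 ± 297 CPM), whereas the list stood at 0.75, 0.25 and 0.35 there and at -0.2, -0.36 and -0.49 in iron-free spl7 rosettes, where 13 fell (camera p = 0.126 with an estimated correlation). Roots had 9 risen genes in the genotype contrast and 7 between pretreatments (camera p = 0.0207 and 0.00412 with an estimated correlation).

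Touch and wound genes were among the largest falls in doubly deficient Col-0 rosettes. A touch or wound response in the control rosettes may contribute: 14 of 17 other genes fell, with a median log2 change of -1.87 (camera p = 0.0137 with an estimated correlation), and the control replicates stood apart, at 178, 24.9 and 41.3 CPM of TCH4, a touch-induced wall gene named after its values were seen. In the genotype contrast of rosettes 14 of 17 fell (camera p = 0.193 with an estimated correlation), in iron-free Col-0 rosettes 7 of 17 (camera p = 0.0344 with an estimated correlation), and in iron-free Col-0 roots 11 of 16 (camera p = 0.0449 with an estimated correlation). In copper-free Col-0 rosettes, which share the controls, no gene was called at a median of -0.89 (camera p = 0.0507 with an estimated correlation). The list rose in 5 of 17 cases in iron-free spl7 rosettes and 5 of 16 in roots (camera p = 0.441 and 0.229 with an estimated correlation).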
